A study of Mus musculus with 18 samples.

How the data were processed

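RNA from dispase-separated dorsal epidermis of mouse embryos at E18.5 was measured on 18 arrays, 5 Hdac3 mutants with 5 controls and 4 Ncor1/Ncor2 mutants with 4 controls. The deposited values are log2 signals per transcript cluster. The submitters' processing notes name RMA (background correction, quantile normalization and median polish) and the Transcriptome Analysis Console, and their versions are not given in the sources used here. The log2 scale is inferred from RMA and from the range of the values, and whether the experiments were normalized jointly is not stated. Nor is the genome build of the probe table given in the sources used here. Samples were grouped by their labels, which also give the litter.

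The table held 34472 array rows. Of these, 23521 named 1 gene symbol, 1820 named several and 9131 were not listed in the probe table. Where a gene had more than 1 row (1082 genes), the row with the highest mean over all arrays was used, which left 22180 genes. Ncor1 and Ncor2 had no row of their own, and Krt5 shared its row with Krt6a. No dim genes were removed. Unnamed rows and rows with several symbols were left out of the gene tests.

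Each experiment was fitted on its own with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without trend), mutant minus control, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The difference between the experiments was a contrast over all 18 arrays with 4 groups. Gene lists were 35 sets written from general knowledge, with 705 of 778 distinct genes measured, and were tested with camera at a preset correlation of 0.01, adjusted over the lists. Each list was also given counts over all genes and adjusted over the list alone. They cover the corepressor complex, basal, spinous, granular and cornified layers, late cornified envelope and small proline-rich genes, barrier lipid synthesis, junctions, stress keratins and alarmins, simple epithelial keratins, hair follicle, cell cycle and its inhibitors, p53, retinoic acid, PPAR and LXR targets, sterol synthesis, clock, interferon, immediate early, oxidative stress and AP-1 genes, oxidative phosphorylation, and fibroblast, melanocyte, immune, endothelial, blood, muscle, nerve, Merkel, gland, adipocyte and sex chromosome markers. The gene comparisons, the lists with their test in each experiment, the rule for naming genes and most alternatives were fixed before the data were examined. The test of list differences between the experiments was added afterwards.

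Genes were named by rule: per experiment the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, up to 4 called members of each list with the largest changes, 6 and 6 genes changed in both experiments, and 5 and 5 genes whose change differed. Xist, Y-linked genes and symbols that are only clone or model numbers were left out of these, while X-linked genes were kept. The largest rises and falls are therefore among the genes the rule could name. Any further gene was chosen after its values were seen, among them Krt15, whose change differed, Crabp2, called in opposite directions, and members named where a list had 5 or fewer calls one way.

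The alternatives were litter, replicate number or sex as a block, quantile normalization, median centring, the dimmest 30% of genes left out, eBayes with trend and robust, array weights, 1 fit of all arrays, every row on its own, a minimum of 2-fold, a plain t-test, the fibroblast marker mean as covariate, camera with estimated correlation, fry, and each array left out in turn. Replicate numbers were not treated as pairs in the main fit. In the Ncor1/Ncor2 experiment control and mutant of the same number shared a litter, while in the Hdac3 experiment those of number 3 did not. In each experiment 2 controls resembled the mutant of their own number most, which does not settle whether the numbers pair the samples. The fit was tested on simulated data with the measured means, independent normal noise and the spreads that limma had drawn towards a common value. It called 77.6% of changes of 0.5 in the Hdac3 and 68.7% in the Ncor1/Ncor2 design and all of 1 or 2, with 6.09% and 5.79% false calls. For the difference, simulated with the Hdac3 spreads on all 18 arrays, it called 31.3% of 0.5 and 95.5% of 1, with 3.82% false. Genes with a wide spread are less well covered by these shares. Skint9 differed by -3.44 in Ncor1/Ncor2 mutants without passing (limma, adjusted p = 0.0574). Camera called 10 of 10 shifted and 0 of 90 unshifted lists in both. The genes of these lists were simulated independently, so the 0 of 90 does not cover real lists whose genes move together. The number of arrays per group limits the precision. Figures were drawn with matplotlib 3.10.9.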

Results

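RNA of the dorsal epidermis of mouse embryos was measured on 18 arrays at E18.5, when the layered skin barrier is being completed. In one experiment 5 embryos labelled Hdac3 mutant were compared with 5 controls. In the other, 4 embryos labelled Ncor1/Ncor2 mutant were compared with 4 controls. Hdac3 is a histone deacetylase, and Ncor1 and Ncor2 (also called NCoR and SMRT) are the corepressor proteins that carry it and switch on its enzyme activity. The Hdac3 embryos came from 2 litters and the Ncor1/Ncor2 embryos from 3, and every litter held both genotypes. All dams had received doxycycline chow at 1 g per kg from E8.5. Values were on a log2 scale, and array medians lay between 4.58 and 4.66. Within a group any pair of arrays correlated across genes at 0.989 or more. The number of arrays limits the precision of every value.

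Hdac3 was the first gene examined, since it checks the labels. Its signal was 8.86 ± 0.118 (SD, n = 5) on a log2 scale in the controls and 7.18 ± 0.336 (SD, n = 5) in the Hdac3 mutants. It fell by 1.68 (SE 0.135), a 3.2-fold change, and every mutant lay below every control (limma, adjusted p = 5.61e-06). In the Ncor1/Ncor2 experiment the signal of Hdac3 was 9.04 ± 0.0296 (SD, n = 4) in controls and 9.06 ± 0.0945 (SD, n = 4) in mutants, a difference of +0.02 (adjusted p = 0.933). Ncor1 and Ncor2 had no array row that named either gene alone, so the labels of the Ncor1/Ncor2 mutants were not checked in this way and both genes were not analysed here. Of the 10 measured members of the fixed corepressor complex list, 3 rose and 1 fell in Hdac3 mutants (4 and 2 adjusted over the list alone), and 3 rose and 0 fell in Ncor1/Ncor2 mutants (5 and 1 adjusted over the list alone). Tbl1xr1 and Tbl1x, WD-repeat partners in the same complex, rose by +1.06 and +0.64 in Ncor1/Ncor2 mutants, and Cops2 rose by +0.48. In Hdac3 mutants the values were +0.36, +0.39 and +0.41, and all passed. The member that fell there was Hdac3 itself, the targeted gene, which the list includes. The call of Tbl1xr1 there ended without control replicate 1, 2, 3 or 4 or mutant replicate 1, 2, 3 or 4 (0.0597 to 0.11), and with litter (0.0631), replicate number (0.0951) or sex (0.0588) as a block. The list as a whole was not called in either experiment (limma camera, adjusted p = 0.662 and adjusted p = 0.0804).

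**Figure D1:**
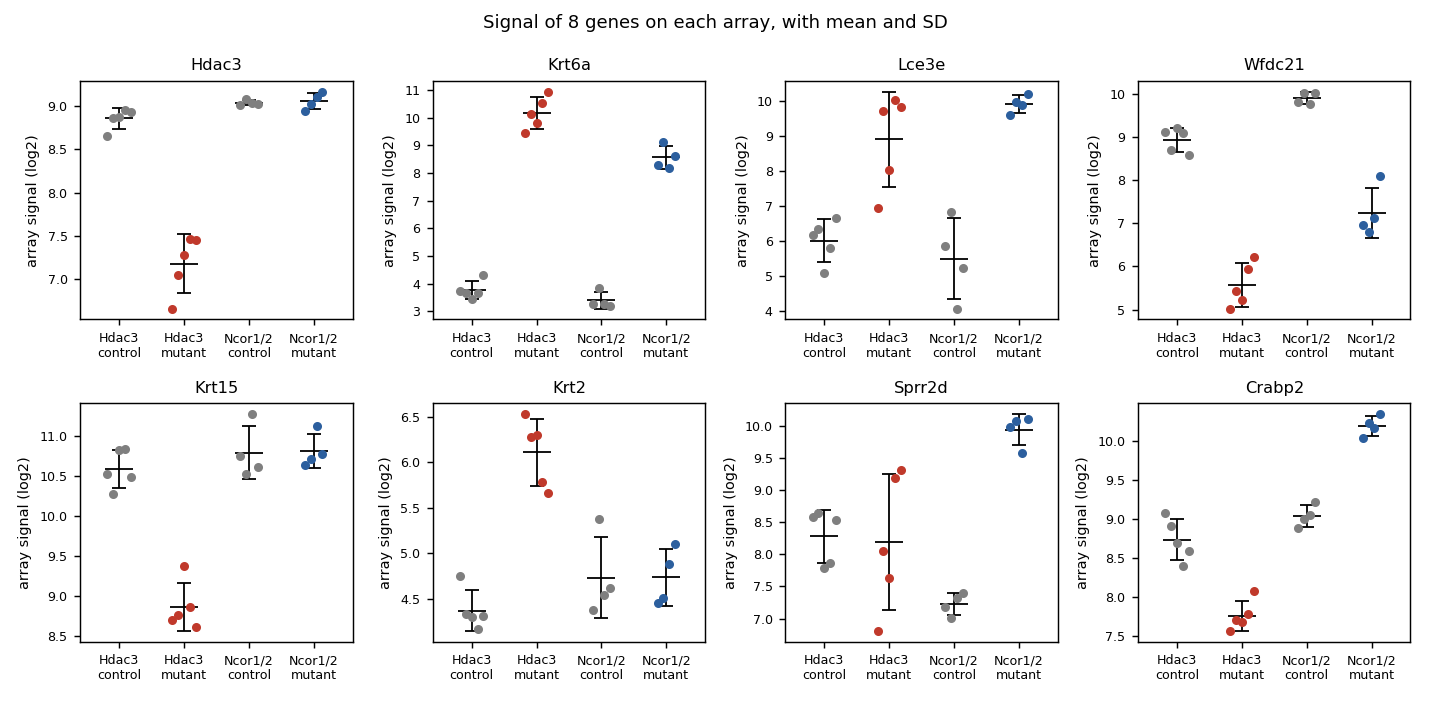
Array signal (log2) of 8 genes in the 4 groups, with a point for each array, a horizontal line for the group mean and bars for the SD. The Hdac3 signal is low only in the 5 Hdac3 mutants, Krt6a is high in the mutants of both experiments, Krt15 and Krt2 move in the Hdac3 experiment, and Sprr2d is higher in the Ncor1/Ncor2 mutants.

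The first comparison asked which genes change in the epidermis when Hdac3 is lost. Among the largest rises were Krt6a and Krt6b, keratins that healthy epidermis between hair follicles makes little of and that appear after wounding or in disease. Krt6a rose from 3.76 ± 0.319 (SD, n = 5) to 10.17 ± 0.584 (SD, n = 5), a log2 change of +6.41 (SE 0.236). The control levels of Krt6a, Krtap13, Lce3f, Prl7b1 and Spink7 lay below the array medians, where signal is near the background, so the sizes and order of these rises are uncertain. Krt6b rose by +5.64 (SE 0.248). The serpin Serpinb3d rose by +3.47, the hair keratin-associated protein gene Krtap13 by +3.30, and the protease inhibitor genes Csta3 and Spink7 by +3.05 and +2.46. The late cornified envelope genes Lce3e and Lce3f rose by +2.90 and +2.64, the prolactin family gene Prl7b1 by +2.68, and Epgn, a ligand of the EGF receptor, by +2.40. Wfdc21, a small secreted protein with a whey acidic protein domain, fell by 3.37 (SE 0.206) from 8.94 ± 0.276 (SD, n = 5) to 5.57 ± 0.504 (SD, n = 5). Other falls were in Ccer2 (-3.08), the cytochrome P450 genes Cyp2b10 (-2.45) and Cyp2f2 (-2.08), the extracellular superoxide dismutase Sod3 (-2.29) and Hal (-2.13), the enzyme that makes urocanic acid from histidine in the outer epidermis. The Wnt receptor Ror1 (-2.08), the oligoadenylate synthetase family member Oas1f (-2.04), the phosphodiesterase Gdpd2 (-2.01) and thrombospondin 1, Thbs1 (-1.94), also fell. For each of these genes all 5 mutants lay outside the range of the 5 controls, and limma's adjusted p was 0.00765 or below. A second, dim row for Cyp2f2 on the array differed by only -0.08.

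Of 22180 genes tested, 1459 were higher and 1258 lower in Hdac3 mutants (limma, Benjamini-Hochberg adjusted p under 0.05), 12.2% of all genes. After quantile normalization 1315 were higher and 1357 lower, and with median centring 1560 and 1083, so the balance of rises and falls depends on the scaling. Most changes were small, with a median size of 0.45 on the log2 scale, and 109 genes rose and 111 fell at least 2-fold. The values of the groups did not overlap for 2285 genes, 10.3% of those tested, where chance gives 0.794%. Within litter 1 alone 587 genes were higher and 517 lower, and 95.1% of them went the same way in litter 2. Within litter 2, 678 were higher and 548 lower, and 92.7% went the same way in litter 1.

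Genes of stressed and wounded epidermis rose in Hdac3 mutants, with the lowest camera p of the 35 lists. Of 35 measured stress keratin and alarmin genes, 17 rose and 0 fell, and 18 rose and 0 fell adjusted over the list alone. After Krt6a and Krt6b the largest rises were in Krt16 (+2.15), the partner keratin of Krt6, and Tslp (+1.60), a cytokine that keratinocytes release when the barrier is damaged. The call of Tslp ended with a variance trend and robust fit (adjusted p = 0.0548). The list was called by limma camera with adjusted p = 7.87e-11, and adjusted p = 0.35 with an estimated correlation. Of 18 late cornified envelope genes, which encode cross-linked proteins of the outermost layer, 10 rose and 1 fell (14 and 1 adjusted over the list alone), led by Lce3e, Lce3f, Lce3d (+2.30) and Lce1k (+1.46). The gene that fell was Lce1m (-0.64). Camera gave adjusted p = 7.36e-08, and adjusted p = 0.379 with an estimated correlation. Of 11 small proline-rich genes, which encode envelope precursors, 4 rose and 0 fell (6 and 0 adjusted over the list alone), namely Sprr2e (+1.73), Sprr1b (+1.27), Sprr2k (+1.06) and Sprr4 (+1.05). The camera test of the list gave adjusted p = 0.000442, and adjusted p = 0.379 with an estimated correlation. Without control replicate 3, mutant replicate 4 or mutant replicate 5, 2 small proline-rich genes were called. The call of Sprr2e ended without control replicate 1, 3 or 4 or mutant replicate 4 or 5 (0.0688 to 0.0851), and that of Sprr4 without control replicate 2 or 3 or mutant replicate 2, 4 or 5 (0.0551 to 0.0672). Both also ended with a variance trend and robust fit (adjusted p = 0.123 for Sprr2e and 0.0747 for Sprr4). Members of the Lce and Sprr2 families and the Krt6 pair have near-identical sequences, and their array rows may share signal.

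Targets of the tumour suppressor p53 rose together. Of 28 measured targets, 13 rose and 0 fell (14 and 1 adjusted over the list alone). They included Ccng1 (+1.76) and Trp53inp1 (+1.25), regulators of the p53 response, and Mdm2 (+1.18), the ligase that degrades p53. The receptor gene Eda2r (+1.08) rose as well. For the list as a set, camera gave adjusted p = 3.75e-08, and adjusted p = 0.00509 with an estimated correlation, so this list alone kept its call in the Hdac3 experiment. Without control replicate 2 or mutant replicate 4, 1 target was called lower. Enzymes of cholesterol synthesis went both ways. Of 19, 10 rose and 4 fell (11 and 4 adjusted over the list alone), with rises in Fdft1 (+0.83), Nsdhl (+0.81) and Cyp51 (+0.79) and falls in Ebp (-0.76), Dhcr7 (-0.70), Pmvk (-0.61) and Tm7sf2 (-0.36). In camera the list had adjusted p = 0.000431 in the upward direction, and adjusted p = 0.396 with an estimated correlation. Of 28 cell junction genes, 11 rose and 5 fell (17 and 7 adjusted over the list alone). The desmosomal cadherins Dsc2 (+0.91) and Dsg1b (+0.71) rose. The gap junction gene Gjb5 (-1.87) and the tight junction genes Cldn23 (-0.87), Ocln (-0.69), Cldn1 (-0.48) and Marveld2 (-0.47) fell. The set was called with adjusted p = 0.00738, and adjusted p = 0.35 with an estimated correlation, and the call also ended after quantile normalization (adjusted p = 0.111). Of 18 spinous layer genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with rises in Grhl3 (+0.91), a transcription factor of barrier formation, Notch1 (+0.86) and Calml3 (+0.58), and a fall in the transcription factor Maf (-0.59). Camera gave adjusted p = 0.0421, and adjusted p = 0.396 with an estimated correlation. That call was also lost with litter as a block (adjusted p = 0.0851), after quantile normalization (0.216), without dim genes (0.101), and without mutant replicate 1, 2 or 3 or control replicate 5 (0.0562 to 0.115).

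Markers of some other cell types also moved. Of 12 melanocyte genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone), among them Mlana (+1.23), Tyr (+1.16), the enzyme that starts melanin synthesis, Kit (+0.93), the receptor melanocytes need to survive, and Slc45a2 (+0.64). The camera test of the list gave adjusted p = 5.65e-06, and adjusted p = 0.379 with an estimated correlation. Without control replicate 1, mutant replicate 3 or mutant replicate 4, 4 melanocyte genes were called. Of 23 markers of immune cells in skin, 1 rose and 8 fell (1 and 9 adjusted over the list alone). The complement gene C1qb (-0.71), the pan-leukocyte gene Ptprc (-0.64) and Laptm5 (-0.61) fell, while Cd68 (+0.64) rose. For the list as a set, camera gave adjusted p = 0.00962, and adjusted p = 0.379 with an estimated correlation. Other cell types gave no call by camera, while the self-contained test fry called the Merkel cell list (adjusted p = 0.0112). For dermal fibroblast markers, of 19 measured, 1 rose and 0 fell, 2 and 1 adjusted over the list alone, adjusted p = 0.216, and the gene was Sparc (+0.37). For endothelial markers, of 10 measured, 1 rose and 0 fell, 1 and 0 adjusted over the list alone, adjusted p = 0.903, and the gene was Pecam1 (+0.33). For neuron and Schwann cell markers, of 8 measured, 1 rose and 0 fell, 1 and 0 adjusted over the list alone, adjusted p = 0.865, and the gene was Mbp (+0.31). The call of Sparc ended without control replicate 1, 2 or 3 or mutant replicate 1, 3, 4 or 5 (0.0601 to 0.0975), that of Pecam1 without control replicate 2, 3, 4 or 5 or mutant replicate 1, 2, 3 or 5 (0.051 to 0.0923), and that of Mbp without control replicate 1, 2, 4 or 5 or mutant replicate 1, 2, 3 or 4 (0.0544 to 0.119). Blocks of replicate number for Sparc (0.0581), and of litter (0.0697) or sex (0.0638) for Mbp, ended these calls as well, as did a variance trend and robust fit for Mbp (0.0585). Camera called the fibroblast list upward without mutant replicate 1 (0.0291). For Merkel cell markers, of 10 measured, 1 rose and 2 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.16, with Chga (-1.80) and Piezo2 (-0.35) falling and Krt18 (+0.57) rising, a call that ended without mutant replicate 1 or 3 or control replicate 4 (0.0562 to 0.0634). A second, dim row for Krt18 went the other way, by -0.20. Piezo2 lay below the array medians in Hdac3 mutants (3.65 to 3.89), so the size of its fall is uncertain. For gland markers, of 10 measured, 2 rose and 1 fell, 2 and 1 adjusted over the list alone, adjusted p = 0.903, for muscle of 14 measured, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.418, for red blood cells of 4 measured, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.903, for adipocytes of 8 measured, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.947, and for sex chromosome genes of 4 measured, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.905. Xist was high in 2 embryos of each Hdac3 group.

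Among the remaining epidermal lists single genes changed strongly without a shift of the list. For the basal layer, of 19 measured, 1 rose and 2 fell, 3 and 2 adjusted over the list alone, adjusted p = 0.903. Krt15, a keratin of basal and follicle stem cells, fell by 1.73 (SE 0.144, adjusted p = 7.6e-06), Postn (-0.65) also fell and the integrin Itga3 (+0.66) rose. For the granular and cornified layer, of 43 measured, 10 rose and 5 fell, 16 and 6 adjusted over the list alone, adjusted p = 0.171. Krt2, a keratin of the upper layers, rose by +1.74 (SE 0.159, limma, adjusted p = 1.67e-05). Its level in controls lay below the array medians except in control replicate 1 (4.76), so the size of this rise is uncertain. The protease Klk5 (-1.49) and the filaggrin relative Flg2 (-0.78) fell. For the hair follicle, of 37 measured, 3 rose and 8 fell, 6 and 9 adjusted over the list alone, adjusted p = 0.903. The stem cell receptor Lgr5 (-1.70) and the Wnt and Bmp antagonist Sostdc1 (-1.27) fell, and the Wnt antagonist Dkk4 (+1.77) rose. A second, dim row for Lgr5 differed by only -0.03. For simple epithelial and periderm keratins, of 8 measured, 2 rose and 1 fell, 3 and 1 adjusted over the list alone, adjusted p = 0.216, with Krt23 (-0.88) falling and Krt13 (+0.43) rising. For barrier lipid synthesis, of 36 measured, 7 rose and 7 fell, 8 and 8 adjusted over the list alone, adjusted p = 0.847, with the lipase Lipk (-1.17) falling and Cyp4f39 (+0.81) rising. Camera called the granular and cornified list upward without mutant replicate 1 (0.036). Counts in these lists moved with single arrays. Without mutant replicate 1, 8 hair follicle genes rose, and without control replicate 1, 3 or 4 or mutant replicate 2, 3 or 5, 5 fell. Without control replicate 1, 3 granular genes and 4 basal genes fell, and without control replicate 5 and mutant replicate 5, in turn, 3 and 2 basal genes rose. Without mutant replicate 1, mutant replicate 3 or control replicate 4, 1 simple epithelial keratin rose.

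The process lists without a camera call were these. For cell cycle genes, of 48 measured, 4 rose and 0 fell, 4 and 0 adjusted over the list alone, adjusted p = 0.157, and camera called the list upward with litter as a block (adjusted p = 0.0161) and without control replicate 3, 4 or 5 (0.0198 to 0.0469). For cell cycle inhibitors, of 14 measured, 4 rose and 5 fell, 4 and 5 adjusted over the list alone, adjusted p = 0.903, with Gadd45g (-1.29) falling and Cdkn1a (+0.77) rising. For the retinoic acid response, of 19 measured, 1 rose and 3 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.171, with falls in Rarres1 (-1.35), Crabp2 (-0.98) and Rdh10 (-0.76). For PPAR targets, of 33 measured, 7 rose and 1 fell, 7 and 1 adjusted over the list alone, adjusted p = 0.16, with rises in Angptl4 (+1.03) and Slc25a20 (+0.70). For fatty acid synthesis and LXR targets, of 20 measured, 4 rose and 1 fell, 5 and 1 adjusted over the list alone, adjusted p = 0.171, with rises in the cholesterol exporters Abca1 (+0.77) and Abcg1 (+0.63). For the circadian clock, of 17 measured, 1 rose and 5 fell, 1 and 5 adjusted over the list alone, adjusted p = 0.0785, with falls in Nr1d1 (-0.79) and Cry2 (-0.68), and this list was called downward with litter as a block (0.0251), after quantile normalization (0.0358), and without mutant replicate 1 or control replicate 3 (0.0483 and 0.0354). For the interferon response, of 25 measured, 3 rose and 0 fell, 3 and 1 adjusted over the list alone, adjusted p = 0.645, led by Cxcl10 (+1.40), whose call ended with a variance trend and robust fit (0.0514). For immediate early and heat shock genes, of 21 measured, 4 rose and 3 fell, 6 and 3 adjusted over the list alone, adjusted p = 0.16, with Ier3 (+1.05) rising and Myc (-0.88) falling. For oxidative stress, of 19 measured, 3 rose and 0 fell, 4 and 0 adjusted over the list alone, adjusted p = 0.143, led by Nqo1 (+0.94). For AP-1 and stratification factors, of 31 measured, 8 rose and 4 fell, 8 and 5 adjusted over the list alone, adjusted p = 0.308, with Pou3f1 (-1.25) falling. For oxidative phosphorylation, of 46 measured, 5 rose and 3 fell, 6 and 4 adjusted over the list alone, adjusted p = 0.177. Counts of called genes moved here too. The 4 cell cycle rises became 1 without control replicate 1, mutant replicate 1 or mutant replicate 4, 2 without control replicate 2 or mutant replicate 3, and 9 without control replicate 5, and 1 cell cycle gene fell without control replicate 2. The immediate early falls became 1 without mutant replicate 2, 4 or 5 or control replicate 2, 3 or 5. The inhibitor falls became 3 without mutant replicate 5, and the retinoic acid rises 0 without control replicate 2, 3 or 4 or mutant replicate 5. In oxidative phosphorylation 3 genes rose without control replicate 2 or mutant replicate 3, 4 or 5, and 1 fell without mutant replicate 1 or 2 or control replicate 3. For the interferon response 1 gene fell without mutant replicate 2 or 5. The fry test called the retinoic acid, PPAR, clock and oxidative stress lists (adjusted p = 0.0112 for each), and the fibroblast mean in the model led to a call of immediate early genes (0.0328). With preset correlation 9 of the 35 lists were called, and other divisions of the same 10 arrays called a median of 6 and up to 11. For each list the divisions with a camera p as small as the real one were counted among 100, the real one included. The count was 1 for p53 targets, 4 for stress keratins and alarmins, and 7 each for sterol synthesis, melanocyte and immune genes. For spinous layer, late cornified envelope, junction and small proline-rich genes it was 8, 9, 10 and 18.

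The second comparison asked the same of the joint loss of Ncor1 and Ncor2. Krtap13 rose from 2.77 ± 0.119 (SD, n = 4) to 9.26 ± 0.339 (SD, n = 4), a log2 change of +6.49 (SE 0.146). Krt6a rose by +5.16 (SE 0.192) and Krt6b by +4.39. The control levels of Krtap13, Krt6a and Lce3f lay below the array medians here too, so the sizes and order of these rises are uncertain. Cornified envelope genes followed, with Lce3f at +4.58, Lce3e at +4.42, Sprr2j-ps at +4.23, Sprr2e at +4.23 and Lce3d at +3.40, together with the protease inhibitor Csta3 at +3.69. Has2, which makes hyaluronan, rose by +4.39 (SE 0.111) from 4.92 ± 0.0558 (SD, n = 4) to 9.31 ± 0.222 (SD, n = 4). The largest falls were again in Wfdc21 (-2.65, SE 0.217) and Ccer2 (-2.56), with Hal (-2.33) and Sod3 (-2.20). Others were Ano7 (-2.50), Chga (-2.36), a granin of neuroendocrine and Merkel cells, and the transcription factor Klf12 (-2.35). Arrdc3 (-2.28), the hair keratin-associated Krtap10-10 (-2.24) and Skint10 (-2.21) also fell. In each of these genes all 4 mutants lay outside the range of the 4 controls, with limma's adjusted p at 0.000144 or below. The mean of Skint10 in mutants (3.99) lay below the array medians, so the size of its fall is uncertain.

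In total 1886 genes were higher and 1389 lower in Ncor1/Ncor2 mutants (limma, Benjamini-Hochberg adjusted p under 0.05), 14.8% of those tested. After quantile normalization 1608 were higher and 1575 lower, and with median centring 2056 and 1229, so the excess of rises depends on the scaling. The median size of these changes was 0.53, and 219 genes rose and 190 fell at least 2-fold. The groups did not overlap for 4179 genes, 18.8%, where chance gives 2.86%. Litter 3, with 2 embryos of each genotype, gave 667 higher and 425 lower genes on its own, and 98.6% of them went the same way in the other litters. Litters 1 and 2 held 1 embryo of each genotype and gave no test of their own.

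Small proline-rich genes were the group that moved most in Ncor1/Ncor2 mutants. Of 11, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with Sprr2e, Sprr2b (+3.27), Sprr2d (+2.71) and Sprr2k (+2.68) in front. Sprr4, the member that did not pass, differed by +0.37 (adjusted p = 0.509). In camera the list had adjusted p = 1.37e-18, and adjusted p = 0.00587 with an estimated correlation, so this list alone kept its call in this experiment. Of 35 stress keratin and alarmin genes, 22 rose and 1 fell (24 and 1 adjusted over the list alone). Beside Krt6a and Krt6b they included Defb14 (+3.19), an antimicrobial defensin, and Ptgs2 (+2.48), the inducible enzyme of prostaglandin synthesis. The member that fell was Il1rn (-0.90), an antagonist of interleukin 1. The set was called with adjusted p = 3.01e-16, and adjusted p = 0.0661 with an estimated correlation. Of 18 late cornified envelope genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone), led by Lce3f, Lce3e, Lce3d and Lce3c (+1.96). Camera gave adjusted p = 9.67e-14, and adjusted p = 0.244 with an estimated correlation. Of 18 spinous layer genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with Krt77 (+2.40) and Grhl3 (+1.20) rising and Maf (-0.96) falling. The camera test of the list gave adjusted p = 0.0434, and adjusted p = 0.457 with an estimated correlation. This call was also lost after quantile normalization (0.24), without dim genes (0.0999), with the fibroblast mean in the model (0.0888), and without mutant replicate 1 or 3 or control replicate 1 or 3 (0.0512 to 0.0875). Of 8 simple epithelial and periderm keratins, 4 rose and 2 fell (5 and 2 adjusted over the list alone). The keratins of wet-surfaced epithelia Krt13 (+2.39) and Krt4 (+1.09) rose, as did Krt18 (+0.58) and Krt7 (+0.40), while Krt23 (-0.54) and Krt20 (-0.38) fell. For the list as a set, camera gave adjusted p = 0.038, and adjusted p = 0.306 with an estimated correlation, and the call ended without control replicate 3 (0.0682). Without mutant replicate 1 or 2 or control replicate 2 or 4, 1 of these keratins fell, as the call of Krt23 ended (0.054 to 0.0844). Krt20 lay below the array medians in the controls (4.01 to 4.28), so the size of its fall is uncertain. Of 28 junction genes, 11 rose and 5 fell (12 and 5 adjusted over the list alone), with rises in Dsc2 (+1.64), Cldn4 (+1.48) and Gjb2 (+1.30) and falls in Cldn23 (-1.39), Gjb5 (-1.24), Ocln (-0.68), Marveld2 (-0.67) and Cldn1 (-0.60). In camera the list had adjusted p = 0.00364, and adjusted p = 0.306 with an estimated correlation.

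Of 19 sterol synthesis genes, 10 rose and 3 fell (13 and 3 adjusted over the list alone), with rises in Nsdhl (+1.12), Lss (+0.84) and Fdps (+0.78) and falls in Dhcr7 (-0.65), Ebp (-0.59) and Pmvk (-0.49). The set was called with adjusted p = 0.000293, and adjusted p = 0.457 with an estimated correlation. Of 20 fatty acid synthesis and LXR target genes, 9 rose and 1 fell (9 and 3 adjusted over the list alone), with the exporters Abcg1 (+1.76) and Abca1 (+1.06), the desaturase Scd1 (+0.90) and fatty acid synthase, Fasn (+0.82), rising and Apoe (-0.49) falling. Camera gave adjusted p = 0.00119, and adjusted p = 0.0858 with an estimated correlation. Of 33 PPAR targets, 8 rose and 1 fell (8 and 2 adjusted over the list alone), led by the lipase inhibitor Angptl4 (+2.40), Acot1 (+1.14) and Cpt1a (+0.94), which brings fatty acids into mitochondria, with a fall in Mgll (-0.41). The camera test of the list gave adjusted p = 0.00901, and adjusted p = 0.306 with an estimated correlation. Of 46 oxidative phosphorylation genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone), by amounts such as +0.59 in Uqcrc2 and +0.55 in Uqcrfs1. For the list as a set, camera gave adjusted p = 0.000123, and adjusted p = 0.511 with an estimated correlation. Of 19 oxidative stress genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with the cystine carrier Slc7a11 (+2.43) and the quinone reductase Nqo1 (+1.42) rising and catalase, Cat (-1.57), falling. In camera the list had adjusted p = 0.016, and adjusted p = 0.306 with an estimated correlation. A second, dim row for Slc7a11 differed by +0.50.

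Of 48 cell cycle genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone), among them Mcm3 (+0.72), part of the replicative helicase, and Rrm2 (+0.65), which makes deoxynucleotides and has a second, dim row that differed by +0.07. The set was called with adjusted p = 1.21e-05, and adjusted p = 0.522 with an estimated correlation, and the self-contained test fry did not call it (adjusted p = 0.0686). Of 28 p53 targets, 11 rose and 3 fell (12 and 4 adjusted over the list alone), with Ccng1 (+1.62), Sesn2 (+1.12) and Mdm2 (+0.99) rising and Sesn1 (-0.80), Btg2 (-0.34) and Psrc1 (-0.34) falling. Camera gave adjusted p = 0.00436, and adjusted p = 0.244 with an estimated correlation. Of these falls, 1 was called without mutant replicate 1, mutant replicate 2 or control replicate 1. Of 17 circadian clock genes, 1 rose and 8 fell (1 and 8 adjusted over the list alone). The clock repressor Nr1d1 (-1.20), Npas2 (-1.02) and Cry2 (-0.76) fell, and Bhlhe40 (+1.18) rose. The camera test of the list gave adjusted p = 0.000367 downward, and adjusted p = 0.244 with an estimated correlation.

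The other lists were not called by camera in Ncor1/Ncor2 mutants. For the basal layer, of 19 measured, 1 rose and 5 fell, 4 and 7 adjusted over the list alone, adjusted p = 0.0579, with Postn (-1.51) and Sox6 (-0.83) falling, and camera called it downward after quantile normalization (0.00905) and without control replicate 2 or 4 (0.00929 and 0.0282). For the granular and cornified layer, of 43 measured, 8 rose and 10 fell, 9 and 12 adjusted over the list alone, adjusted p = 0.951, with Klk5 (-1.69) falling and Rptn (+1.56) rising. For the hair follicle, of 37 measured, 9 rose and 9 fell, 10 and 10 adjusted over the list alone, adjusted p = 0.39, with Dkk4 (+2.16) rising and Lgr5 (-1.39) falling, where a second, dim row for Lgr5 differed by -0.15. For barrier lipid synthesis, of 36 measured, 10 rose and 5 fell, 11 and 7 adjusted over the list alone, adjusted p = 0.472, called without control replicate 2 (0.023). For cell cycle inhibitors, of 14 measured, 2 rose and 6 fell, 3 and 6 adjusted over the list alone, adjusted p = 0.375, with Gadd45g (-1.32) falling. For the retinoic acid response, of 19 measured, 5 rose and 2 fell, 5 and 2 adjusted over the list alone, adjusted p = 0.472, with Stra6 (+1.35), Crabp2 (+1.15) and Rarb (+0.84) rising and Rarres1 (-2.07) and Rdh10 (-0.52) falling. For the interferon response, of 25 measured, 2 rose and 2 fell, 2 and 2 adjusted over the list alone, adjusted p = 0.89, with Cxcl10 (+1.91) rising and Irf7 (-0.80) falling. For immediate early and heat shock genes, of 21 measured, 4 rose and 4 fell, 6 and 6 adjusted over the list alone, adjusted p = 0.989, with Hspa1a (+1.20) rising and Myc (-0.84) falling. For AP-1 and stratification factors, of 31 measured, 7 rose and 5 fell, 8 and 8 adjusted over the list alone, adjusted p = 0.296, with Grhl3 (+1.20) rising and Pou3f1 (-0.89) falling, called downward after quantile normalization (0.0262). Melanocyte markers gave no call, of 12 measured, 1 rose and 0 fell, 1 and 0 adjusted over the list alone, adjusted p = 0.817, the gene being Tyrp1 (+1.03). For dermal fibroblast markers, of 19 measured, 0 rose and 2 fell, 0 and 2 adjusted over the list alone, adjusted p = 0.39, namely Fn1 (-1.08) and Vim (-0.39), and the call of Vim ended with litter as a block (0.0552), the replicate block (0.0652), and without mutant replicate 1 or 3 or control replicate 1 or 3 (0.0601 to 0.101). For immune cells, of 23 measured, 4 rose and 1 fell, 4 and 1 adjusted over the list alone, adjusted p = 0.827, with H2-Ab1 (+0.99) rising. For Merkel cells, of 10 measured, 1 rose and 2 fell, 1 and 2 adjusted over the list alone, adjusted p = 0.256, with Chga falling. For glands, of 10 measured, 3 rose and 1 fell, 4 and 1 adjusted over the list alone, adjusted p = 0.113, led by Mgst1 (+1.89), and called with the replicate block (0.0444) and without control replicate 2 (0.0478). For endothelial cells, of 10 measured, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.93, for red blood cells of 4 measured, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.753, for neurons and Schwann cells of 8 measured, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.951, for muscle of 14 measured, 0 rose and 1 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.492, for adipocytes of 8 measured, 1 rose and 0 fell, 1 and 1 adjusted over the list alone, adjusted p = 0.93, and for sex chromosome genes of 4 measured, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.951. Xist was high in 3 embryos of each group. Counts moved with single arrays for several of these lists. Basal rises became 0 without mutant replicate 2 or 3 or control replicate 2 and 4 without control replicate 3, AP-1 list falls 8 without control replicate 3, and interferon falls 1 without mutant replicate 2, 3 or 4 or control replicate 1 or 2. Immune falls became 0 without mutant replicate 2 or 3 or control replicate 1, 2 or 3 and 3 without control replicate 4. Muscle falls became 0 without mutant replicate 2 or 4 or control replicate 1 or 3, and adipocyte rises 0 without mutant replicate 1, 3 or 4 or control replicate 2. Without control replicate 1, 2 melanocyte genes rose. The fry test also called the corepressor (0.0113), cell cycle inhibitor (0.0342), Merkel and gland lists (0.0359 for both). With preset correlation 14 of the 35 lists were called, and other divisions of the same 8 arrays called a median of 6 and up to 16. Divisions with a camera p as small as the real one were counted among all 35, the real one included. The count was 1 for small proline-rich, late cornified envelope, stress keratin, and fatty acid and LXR genes. It was 2 for p53 targets and simple epithelial keratins, 3 for junction, sterol, clock and oxidative stress genes, and 4 for spinous layer genes. For PPAR targets, oxidative phosphorylation and cell cycle genes it was 5, 7 and 9.

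**Figure D2:**
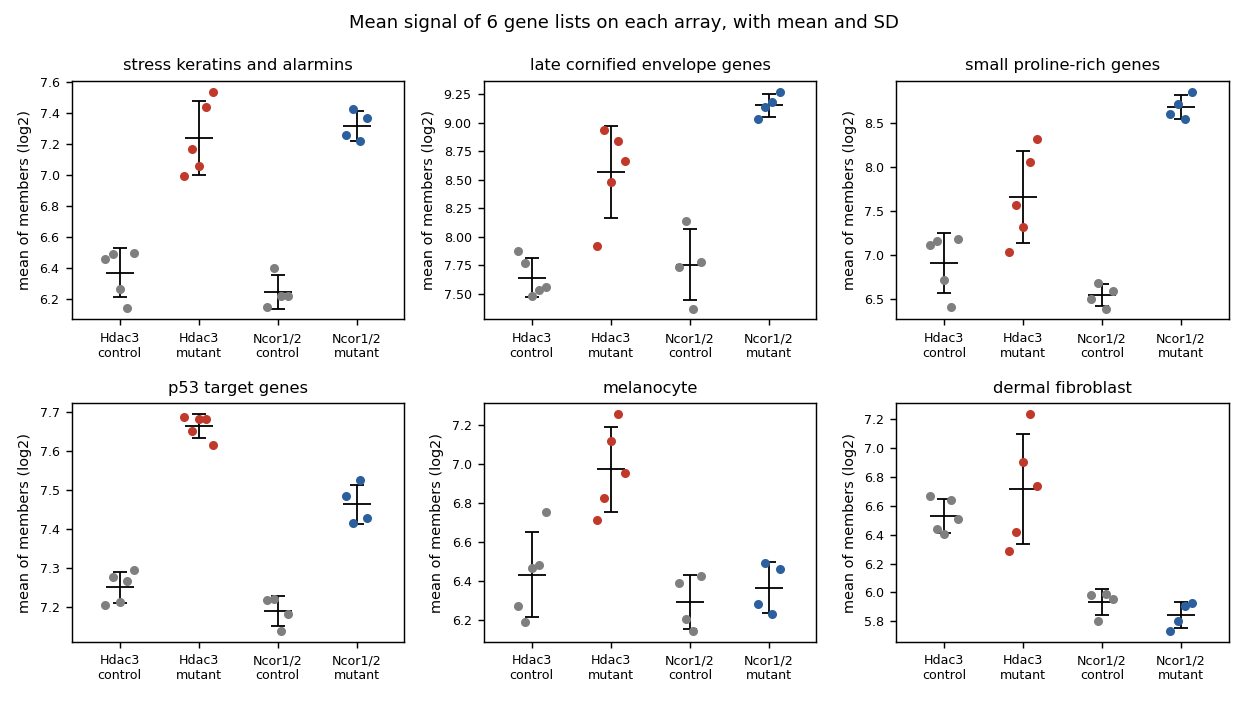
Mean log2 signal of the measured members of 6 gene lists on each array, with group means (lines) and SD (bars). The stress, late cornified envelope, small proline-rich and p53 target means are higher in mutants of both experiments, the melanocyte mean is 6.98 in Hdac3 mutants against 6.43 in their controls and 6.37 in Ncor1/Ncor2 mutants against 6.29, and the fibroblast means of the groups overlap within each experiment.

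The title of the study names a dependence of Hdac3 on NCoR and SMRT, so the overlap of the changes was measured next. Krt6a, Krt6b, Krtap13, Serpinb3d, Csta3 and Lce3e rose in both experiments by at least +2.90, and Wfdc21, Ccer2, Sod3, Hal, Cyp2f2 and Gdpd2 fell in both by at least 2.01. The second, dim row for Cyp2f2 differed by -0.08 in Hdac3 and -0.35 in Ncor1/Ncor2 mutants. Serpinb3d rose by +3.47 in Hdac3 mutants and +3.27 in Ncor1/Ncor2 mutants, and Sod3 changed by -2.29 and -2.20. In all, 910 genes rose in both (124 expected if the calls were independent) and 722 fell in both (78.8 expected). Only 3 genes were called in opposite directions. Of the genes changed in Hdac3 mutants, 95.3% went the same way in Ncor1/Ncor2 mutants, called or not, and of those changed in Ncor1/Ncor2 mutants, 95.1% went the same way in Hdac3 mutants. Across all genes the log2 changes correlated with a Pearson r of 0.756 and a Spearman rho of 0.576, where genes are not independent replicates. Of the 1632 genes called in both in one direction, 1157 had the larger change in Ncor1/Ncor2 mutants. The experiments shared no control arrays or litters. The expected counts treat all genes tested as equally likely to be called, dim ones included. Which transgenes the controls carried is not given in the labels. An effect of the recombination system common to both experiments therefore cannot be told apart from the deletions in this overlap.

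**Figure D3:**
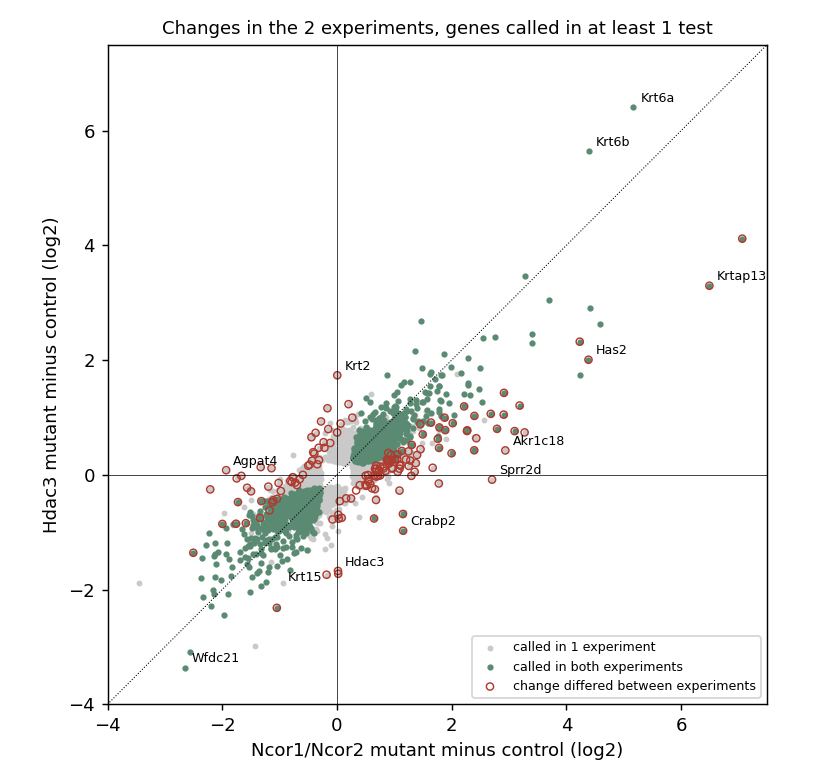
Log2 change of each called gene in Ncor1/Ncor2 mutants (horizontal) and in Hdac3 mutants (vertical), with grey for genes called in 1 experiment, green for both, red rings for genes whose change differed between experiments, and a dotted line where both changes are equal. Most points lie in the quadrants of equal sign, with Krt15, Krt2 and Hdac3 on the vertical axis and Sprr2d near the horizontal one.

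The difference between the experiments was then tested gene by gene over all 18 arrays. Krt15 fell in Hdac3 mutants (-1.73) but was 10.80 ± 0.333 (SD, n = 4) in controls and 10.82 ± 0.215 (SD, n = 4) in mutants of Ncor1 and Ncor2, and the changes differed by -1.75 (SE 0.23, limma, adjusted p = 0.00033). Krt2 rose in Hdac3 mutants and differed by +0.01 in Ncor1/Ncor2 mutants (difference +1.73, SE 0.278, adjusted p = 0.00266). Its level in most Hdac3 controls lay below the array medians, so the size of this difference is uncertain. Crabp2, which binds retinoic acid in the cell, fell in Hdac3 mutants (-0.98) and rose in Ncor1/Ncor2 mutants (+1.15), a difference of -2.13 (SE 0.172, adjusted p = 1.17e-06). Lower changes in Hdac3 mutants were found for Krtap13 (-3.20), Sprr2d (-2.79), Sprr2b (-2.53), the steroid-metabolising enzyme Akr1c18 (-2.51) and Has2 (-2.38). Among them Sprr2d was 8.28 ± 0.417 (SD, n = 5) in Hdac3 controls and 8.19 ± 1.06 (SD, n = 5) in Hdac3 mutants, against 7.23 ± 0.173 (SD, n = 4) and 9.94 ± 0.242 (SD, n = 4) in the other experiment. Agpat4, an acyltransferase of phospholipid synthesis, fell in Ncor1/Ncor2 mutants (-1.93) and differed by +0.08 in Hdac3 mutants (difference +2.01, adjusted p = 0.000147). Skint10, Angpt2 and Spink1 had positive differences too, of +1.96, +1.69 and +1.65. The call of Skint10 was lost with a variance trend and robust fit (adjusted p = 0.0584). Its mean in Ncor1/Ncor2 mutants lay below the array medians, so the size of that difference is uncertain. In total 151 genes differed, 50 with the higher change in Hdac3 mutants and 101 with the lower, and 2125 at an unadjusted p under 0.05. Of the 151, 46 had been called in both experiments in one direction and 3 in opposite ones. The experiments were separate sets of litters, so genotype and experiment cannot be told apart in these differences.

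Of the 35 lists, 21 shifted between the experiments by camera with preset correlation. Small proline-rich genes rose less in Hdac3 mutants, with a median difference of -1.26 and 5 differing members (adjusted p = 1.31e-13, and adjusted p = 0.0537 with an estimated correlation). Between mutants and controls the list mean differed by +0.17 (SE 0.201) in litter 1 and +1.42 (SE 0.306) in litter 2 of the Hdac3 experiment. With litter 2 alone the difference of the list means went from -1.39 to -0.72, with a 95% interval of -1.65 to 0.22 that includes 0. Melanocyte genes had a median difference of +0.50, with Kit, Tyr and Mlana differing singly (adjusted p = 2.16e-07, and adjusted p = 0.159 with an estimated correlation). Oxidative phosphorylation genes were lower by a median of -0.16 in that difference, with 0 differing singly (adjusted p = 3.41e-05, and adjusted p = 0.256 with an estimated correlation). For p53 targets the median difference was +0.10 (adjusted p = 0.00647, and adjusted p = 0.0708 with an estimated correlation). With an estimated correlation 0 of the 35 lists passed. The fibroblast marker mean was 6.53 ± 0.119 (SD, n = 5) in Hdac3 controls and 5.93 ± 0.089 (SD, n = 4) in Ncor1/Ncor2 controls. The experiments thus differed in these markers, and whether tissue preparation or array processing underlies this was not tested.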

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

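The search for outlying samples, the gene-by-gene difference between the experiments, the fit of every probe set and the other divisions of the arrays were planned, while the tests of list differences, of litter differences and of explanations were chosen after results were seen.

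A sample far from the others of its group was sought in 788 groups of values, and 44 were found. Chance alone gives about 1 in 20 groups, or 39.4 here, close to the number found. Among Ncor1/Ncor2 controls the list means far from the others were corepressor complex in replicate 3 (8.07, nearest other 8.22), PPAR target genes in replicate 4 (5.85, nearest other 5.94), adipocyte in replicate 3 (4.78, nearest other 4.42) and sex chromosome genes in replicate 1 (6.61, nearest other 5.56). Among Hdac3 controls the list means far from the others were sterol synthesis in replicate 4 (8.90, nearest other 8.61). Among Ncor1/Ncor2 mutants the list means far from the others were endothelial cell in replicate 1 (4.26, nearest other 4.34) and adipocyte in replicate 4 (4.56, nearest other 4.45). Among Ncor1/Ncor2 controls the genes were Abca1 in replicate 1 (6.74, nearest other 6.28), Cldn23 in replicate 2 (7.37, nearest other 6.62), Cyp2b10 in replicate 2 (8.61, nearest other 7.56), Dsc2 in replicate 4 (5.10, nearest other 4.95), Gjb5 in replicate 2 (8.16, nearest other 7.55), Hspa1a in replicate 2 (6.05, nearest other 6.56), Krt16 in replicate 3 (10.35, nearest other 9.35), Krt20 in replicate 3 (4.01, nearest other 4.24), Krt6a in replicate 2 (3.85, nearest other 3.28), Piezo2 in replicate 4 (3.55, nearest other 3.88), Psrc1 in replicate 4 (5.60, nearest other 5.79), Rdh10 in replicate 3 (6.44, nearest other 6.75), Tbl1x in replicate 1 (8.91, nearest other 8.79) and Xist in replicate 1 (4.47, nearest other 11.04). Among Ncor1/Ncor2 mutants the genes were Abcg1 in replicate 1 (8.11, nearest other 7.58), Btg2 in replicate 4 (11.03, nearest other 10.83), Cops2 in replicate 2 (9.72, nearest other 9.52), Flg2 in replicate 4 (11.11, nearest other 10.74), Gadd45g in replicate 1 (6.005, nearest other 6.28), Gjb5 in replicate 1 (5.82, nearest other 6.57), Npas2 in replicate 2 (5.06, nearest other 4.72), Nsdhl in replicate 4 (9.23, nearest other 9.77), Psmd12 in replicate 2 (9.77, nearest other 9.58), Ptgs2 in replicate 1 (8.51, nearest other 8.96), Ptprc in replicate 4 (5.14, nearest other 4.43), Slc45a2 in replicate 1 (6.26, nearest other 6.44) and Xist in replicate 1 (4.13, nearest other 10.89). Among Hdac3 controls the genes were Krt2 in replicate 1 (4.76, nearest other 4.33), Krt4 in replicate 5 (3.50, nearest other 3.72), Slc7a11 in replicate 2 (4.97, nearest other 5.55), Tyr in replicate 5 (5.51, nearest other 4.89) and Uqcrfs1 in replicate 5 (6.25, nearest other 6.17). Among Hdac3 mutants the genes were Mgll in replicate 3 (6.18, nearest other 5.74), Piezo2 in replicate 1 (3.65, nearest other 3.83), Rarb in replicate 3 (5.401, nearest other 4.83), Sprr1b in replicate 3 (12.48, nearest other 12.55) and Uqcrc2 in replicate 4 (9.65, nearest other 9.56). Xist is low in male embryos, so a lone male among females is found this way, and the sex chromosome list mean stood out in the same control. In Hdac3 mutants Xist was high in 2 embryos and low in 3.

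The log2 changes of single genes differed between the experiments by a test of the difference itself, for 151 genes in all. Among genes named in the text the change was higher in Hdac3 mutants for Agpat4 (+2.01), Angpt2 (+1.69), Ano7 (+1.15), Cat (+1.34), Kit (+1.21), Kitl (+1.10), Krt2 (+1.73), Mlana (+1.03), Skint10 (+1.96), Spink1 (+1.65), Tyr (+1.33), Vim (+0.77). It was lower for Abcg1 (-1.13), Akr1c18 (-2.51), Angptl4 (-1.37), Crabp2 (-2.13), Defb14 (-1.98), Dsc2 (-0.73), Gjb2 (-0.78), Has2 (-2.38), Hdac3 (-1.70), Krt13 (-1.97), Krt15 (-1.75), Krt4 (-0.92), Krtap13 (-3.20), Mgst1 (-1.11), Slc7a11 (-1.79), Sprr2b (-2.53), Sprr2d (-2.79), Sprr2j-ps (-1.91), Sprr2k (-1.62), Stra6 (-1.30), Tbl1xr1 (-0.70). Krt4 lay below the array medians in Hdac3 controls (3.50 to 3.81), so the size of its difference is uncertain. At preset correlation these lists differed between the experiments by limma camera, with the adjusted p in parentheses: corepressor complex (0.00647), basal layer (0.0103), granular and cornified layer (0.0178), late cornified envelope genes (0.00077), small proline-rich genes (1.31e-13), stress keratins and alarmins (0.0318), simple epithelial and periderm keratins (0.00517), cell cycle (0.00077), p53 target genes (0.00647), cell cycle inhibitors (0.013), retinoic acid response (0.00778), PPAR target genes (0.00755), fatty acid synthesis and LXR targets (0.00647), circadian clock (0.013), oxidative stress response (0.0318), AP-1 and stratification transcription factors (0.0118), oxidative phosphorylation (3.41e-05), dermal fibroblast (0.00647), melanocyte (2.16e-07), immune cells of skin (0.00692), sweat and sebaceous gland (0.00734). Hdac3 itself, the targeted gene, is among the 2 differing members of the corepressor list, so that difference is partly built in. None of these lists passed with an estimated correlation, where the lowest adjusted p values were 0.0537 for small proline-rich genes and 0.0708 for p53 targets. Between the litters of the Hdac3 experiment the change differed for 2 genes, Hs3st1 (+1.48 higher in litter 2, adjusted p = 0.0122), a heparan sulfate sulfotransferase, and Il33 (+1.58 higher in litter 2, adjusted p = 0.0436), an alarmin, and at an unadjusted p under 0.05 for 1841.

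Array probes outside the gene comparisons also carried a signal. Of 9131 probe sets without a gene name, 408 (4.47%) changed in Hdac3 mutants and 483 (5.29%) in Ncor1/Ncor2 mutants by the same limma fit. Of 1820 that name several genes, 134 and 154 changed.

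Whether other divisions of the arrays give results as large was counted. For the genes changed in Hdac3 mutants (2717) chance can be excluded, since 1 of 100 divisions, the real one, gave as many and the highest other gave 1. It can also be excluded for Ncor1/Ncor2 mutants (3275, 1 of 35, highest other 4) and for genes whose change differed (151, 1 of 100, highest other 7). For genes changed in both in one direction (1632, 1 of 100, highest other 0) the count decides nothing further. Other divisions called at most 1 and 4 genes per experiment, so they had almost none to share. For the number of lists called at preset correlation chance cannot be excluded. In the Hdac3 experiment 21 of 100 divisions called at least the real 9 (highest other 11), and in the Ncor1/Ncor2 experiment 3 of 35 called at least 14 (highest other 16).

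Of 12 melanocyte genes 6 rose in Hdac3 mutants, and the call of the list was lost with an estimated correlation (adjusted p = 0.379). Dermis carried along is not settled. With the fibroblast mean in the model the mean change of the markers was +0.45 (SE 0.119), against +0.54 (SE 0.139) without it. The fibroblast mean itself differed by +0.19 (SE 0.178) between Hdac3 mutants and controls. Most of the melanocyte change thus remained, but 1 marker mean may capture carried tissue only in part. More melanocytes and more RNA per melanocyte cannot be told apart, since the 10 of 10 markers above the median level with changes above 0 restate the rise. Kitl, the ligand that draws Kit-bearing melanocytes, rose by +0.73 (adjusted p = 0.00322) and differed by -0.37 (adjusted p = 0.0647) in Ncor1/Ncor2 mutants, a difference of +1.10 (adjusted p = 0.0077), so a larger supply of it is a candidate explanation.

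The mean change of small proline-rich genes was lower in Hdac3 than in Ncor1/Ncor2 mutants, by -1.39 (SE 0.295), with 4 and 10 of 11 members called higher and 5 differing, but the list difference was lost with an estimated correlation (adjusted p = 0.0537), as was the call in Hdac3 mutants (adjusted p = 0.379). An upper limit of the array signal is argued against for the list mean only. The mean level in Hdac3 mutants lay below that in Ncor1/Ncor2 mutants by -1.02 (95% interval -1.66 to -0.38). A mean cannot show this for single bright members such as Sprr1b (12.48 in Hdac3 mutant replicate 3). Whether the experiments were normalized jointly is not stated. Litter 1 of the Hdac3 experiment may account for part: its change was +0.17, that of litter 2 +1.42, and with litter 2 alone the difference was -0.72 (95% interval -1.65 to 0.22), which leaves it open. Signal shared by near-identical Sprr2 copies cannot be told apart either, as the 4 members outside Sprr2 had a median difference of -0.73 and 1 of them differed singly.

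The mean change of p53 targets was +0.41 in Hdac3 mutants, where 13 of 28 rose, and +0.27 in Ncor1/Ncor2 mutants, where 11 rose and 3 fell. With an estimated correlation the call was kept in Hdac3 mutants (adjusted p = 0.00509) and lost in Ncor1/Ncor2 mutants (adjusted p = 0.244). Stress during handling cannot be told apart, because 4 immediate early and heat shock genes fell in Ncor1/Ncor2 mutants while 4 rose. The recombination system alone, acting equally in both experiments, stays open: these means differed by +0.14 (SE 0.0386), but the list difference was lost with an estimated correlation (adjusted p = 0.0708) and 0 of 28 members differed singly by limma. The labels do not say which transgenes the controls carried.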

How the results depend on the processing

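The settings with embryo sex or the fibroblast mean in the model, lists with 1 array left out, and the difference among genes above the median level were chosen after the data were seen, and the others were fixed before.

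With 1 array left out, between 2059 and 2769 genes were called in Hdac3 mutants (2717 with all), 2513 to 3085 in Ncor1/Ncor2 mutants (3275), 1337 to 1695 in both (1632) and 109 to 159 in the difference (151). The lists called ranged from 8 to 11 and from 12 to 17. With litter as a block 2536 of the 2717 and 3060 of the 3275 genes kept their call, after quantile normalization 2382 and 2865, with the replicate block 2339 and 2966, and with the fibroblast mean in the model, which fits a further term, 2173 and 2319. No called gene changed sign in any of these.

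A minimum of 2-fold, which is stricter by construction, left 109 higher and 111 lower genes in Hdac3 mutants, 220 in all, and 219, 190 and 409 in Ncor1/Ncor2 mutants, with 161 in both. A plain t-test, which does not share the spread between genes, called 915 higher genes and 1760 in all in Hdac3 mutants, and 844 lower genes and 2141 in all in Ncor1/Ncor2 mutants. With an estimated correlation, which allows for genes of a list moving together, 1 list was called in each experiment (p53 targets in Hdac3, small proline-rich genes in Ncor1/Ncor2 mutants). With fry 14 lists were called in Hdac3 mutants, and the cause was not tested. For dim genes the array signal lies near the background, and with the dimmest 30% left out 2626 of the 2629 Hdac3 calls still tested were kept. Leaving genes out eases the adjustment (2795 genes called, against 2717), so this does not test an effect of the background on the calls.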

Other observations

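The tests in this part, of gene families and of neighbouring genes, were all chosen after the results were seen, as were the genes named here.

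Genes were grouped into families by the stem of their symbol, and 339 families of at least 8 genes were tested with camera in each experiment. With preset correlation 17 were called in Hdac3 and 30 in Ncor1/Ncor2 mutants. With an estimated correlation 0 were called, the lowest adjusted p values being 0.535 and 0.0659. Proteasome regulatory subunit genes (Psmd) rose in 7 of 14 cases in Hdac3 and 10 of 14 in Ncor1/Ncor2 mutants, for example Psmd12 by +0.53 and +0.59 and Psmd5 by +0.51 and +0.88. Mitochondrial ribosome genes (Mrpl) rose in 11 and 15 of 43 cases. Genes of the Skint family fell in 7 and 5 of 11 cases, among them Skint7 by -1.27 and -0.78 and Skint8 by -0.97 and -0.92. Skint9 and Skint3, which did not pass in Ncor1/Ncor2 mutants, varied widely among the controls there, with SDs of 2.93 and 2.04. The airway-type serine protease genes Tmprss11a and Tmprss11g rose by +2.39 and +1.89 in Hdac3 and +2.55 and +1.98 in Ncor1/Ncor2 mutants.

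Neighbours on a chromosome may change together, beyond members of a family. Among 16712 neighbouring pairs of different families that do not overlap, 243 changed the same way in Hdac3 mutants, where 10000 random orders within 20 levels of expression gave a median of 166 and at most 215 (permutation p = 1e-04, the smallest these can give). In Ncor1/Ncor2 mutants 313 did, against a median of 248 and at most 316 (permutation p = 2e-04). Whether shared regulation or shared probes underlie this was not tested.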
